A study of Mus musculus with 12 samples.

How the data were processed

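RNA was measured in 12 libraries of mouse bone marrow cells, 3 replicates in each of 4 sorted fractions (H2BHi-MMPLo, H2BHi-MMPHi, H2BLo-MMPLo and H2BLo-MMPHi). Per the labels' protocols, c-Kit-positive cells of pooled animals were enriched, LSK-SLAM cells were sorted by H2B and mitochondrial membrane potential, and the sorted cells were cultured for 15 h in serum-free StemSpan with SCF and TPO at 100 ng/ml each. Per the labels' protocols, RNA was prepared with the Smart-seq v4 kit, amplified with the Ovation RNA-seq v2 kit, turned into libraries with Nextera XT and sequenced in pairs on a NovaSeq instrument with 50 × 1000000 read pairs as the target. The series design text gives 5 ng of RNA as input. The labels do not say whether replicates are separate animals, pools or cultures, and p-values therefore measure only the spread between these libraries.

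Per the submitters' processing notes, kallisto was used with the mm10 genome, with no version, annotation or counting rule stated. The authors deposited 1 table with a log2 value for 35869 gene symbols in each library. The name of the table calls the values TPM, but every value is the log2 of a whole number plus 1 to 4 decimals, and these whole numbers sum to 46283467 to 54669475 per library. Of the whole numbers from 2 to 31, 66.6 to 70.2% are even in each library, as when both mates of a pair are counted. The deposited log2 values were therefore taken as unscaled reads per gene. No scaling between libraries was seen in them, and what the authors did beyond this is not stated. At these depths counting error is small beside the spread between replicates: the chi-square per degree of freedom of replicate pairs was 18.7 to 192.3 (median 33.6).

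The whole numbers were recovered, divided by each library's total and given as CPM, counts in units of 1000000 reads. Genes with a mean of at least 1 CPM over the 12 libraries were kept (13317; 6695 of the 35869 genes were at 0 in every library), and log2(CPM + 1) was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 12 libraries, which leaves 8 residual degrees of freedom, and with empirical Bayes moderation with a trend on mean expression. All tests are two-sided. There were 7 comparisons: MMPHi minus MMPLo in H2BHi and in H2BLo cells, H2BLo minus H2BHi in MMPLo and in MMPHi cells, the averages of each pair, and their interaction. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The planned test assumed TPM; since the table holds log2 reads, CPM took the place of TPM in the scaling, in the filter and in the rule for named genes, and the model was kept. Gene positions are those of GRCm38.p6 (mm10) in RefSeq, matched by symbol for 12500 of the 13317 genes. The counting rule for genes that share sequence is not stated, so values of near-identical families (histone, globin and guanylate-binding protein genes) are uncertain.

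The comparisons, gene lists, rule for named genes and alternatives were chosen before the data were examined, apart from those said to be added later. There were 36 gene lists: HSC identity genes, multipotent progenitor markers, CDK inhibitors and quiescence regulators, immediate early genes, G1/S and DNA replication genes, G2/M and mitosis genes, MYC and ribosome biogenesis genes, cytosolic ribosomal protein genes, mitochondrial ribosome and protein quality control genes, nuclear-encoded respiratory chain genes, mitochondrially encoded genes, TCA cycle and pyruvate dehydrogenase genes, glycolysis genes, fatty acid oxidation genes, lysosome genes, autophagy and mitophagy genes, mitochondrial dynamics and biogenesis genes, mitochondrial calcium uptake and VDAC genes, dye efflux transporters, cholesterol synthesis genes, ATF4 and amino acid response genes, ER protein folding genes, antioxidant genes, hypoxia response genes, interferon response genes, p53 target genes, NF-kB response genes, STAT5 and cytokine feedback genes, HSC ageing genes, and markers of megakaryocytes and platelets, erythroid cells, granulocytes and monocytes, lymphoid cells, mast cells and basophils, macrophages, and stroma and endothelium. The 35 lists with at least 3 genes tested were tested by camera in limma with a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the lists of each comparison. Each was also tested by camera with a correlation estimated from the data and by fry, which asks whether a list's genes move 1 way on balance.

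Genes are named by a fixed rule. In the 4 comparisons within a level these are up to 10 genes per direction with the largest fold change among those with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the 6 values, leaving out genes whose symbols mark them as predicted genes, clones or pseudogenes (Mx2, a transcribed pseudogene in RefSeq, has no such symbol and was kept). In the averaged comparisons and the interaction they are up to 5 per direction, with no overlap within each pair of groups for the averages. Where fewer than 5 passed in a direction, such genes of smallest p could be added and said not to pass. Of each list up to 4 members with the smallest p could be named, and 20 markers of HSC state, cycling and lineage (Procr, Slamf1, Cd48, Flt3, Cd34, Hlf, Mecom, Mllt3, Vwf, Itga2b, Mki67, Cdk6, Cdkn1c, Ccnd1, Myc, Tfrc, Slc2a1, Tfeb, Mpo, Gata1) were fixed whatever their test.

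The alternatives were a pseudocount of 0.1 or 5, no filter on low values, a mean of at least 5 CPM, quantile normalization, median centring, scaling without mitochondrially encoded and ribosomal protein genes, moderation without trend or with the robust option (statmod 1.5.0), library weights, the replicate number as a block, the compared groups alone, each library left out in turn, and the estimated correlation. Added after the data were seen were voom weights, median-of-ratios size factors, and leaving out H2BHi-MMPLo 1 and 2 together. The procedure was tested on simulated counts. For MMP in H2BHi cells, over 13300 genes, it recovered 20, 40, 72 and 92% of 50 genes changed by each of 1.5, 2, 3 and 5 fold, with 12 false among 130 calls (9.23%). For the averaged MMP comparison, over 13279 genes, it recovered 38, 70, 82 and 94%, with 6 false among 159 calls (3.77%). A shifted list was called in both, with 0 and 1 other lists. This does not gauge false list calls: other splits of real libraries gave up to 16 for MMP averaged. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).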

Results

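RNA of mouse haematopoietic stem cells (HSCs) was sequenced in 12 libraries. The cells came from bone marrow of pooled animals, were enriched for the receptor c-Kit, and carried the LSK-SLAM surface phenotype by which HSCs are sorted. They were parted by the level of H2B, a core histone, and by mitochondrial membrane potential (MMP), the voltage across the inner mitochondrial membrane, and were kept for 15 h in serum-free medium with stem cell factor and thrombopoietin. The labels do not say what the H2B level records, nor whether it is that of the cells' own histone. The 4 groups, H2BHi-MMPLo, H2BHi-MMPHi, H2BLo-MMPLo and H2BLo-MMPHi, had 3 libraries each, and a library is named here by its group and replicate number (H2BHi-MMPLo 1). Libraries held 46283467 to 54669475 reads. In units of 1000000 reads, mean totals were 51.7 ± 4.25 (SD, n = 3) in H2BHi-MMPLo, 49.7 ± 1.52 in H2BHi-MMPHi, 49.8 ± 4.36 in H2BLo-MMPLo and 50.0 ± 3.45 in H2BLo-MMPHi. Values are given as CPM, the reads of a gene per such unit of its library's total (mean ± SD, n = 3 per group). Fold changes come from log2(CPM + 1), which understates changes of genes with few reads. Adjusted p-values of genes are from limma and those of gene lists from camera, and all of them measure only the spread between these libraries.

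H2BHi-MMPLo 1 stood apart from the other 11 libraries. Its score on the first principal component (28.6% of the variance) was −79.0, against −14.3 to 27.0 in the others. This library had reads for 21319 genes (19013 to 20080 in the others), 0.867% of reads from mitochondrially encoded genes (1.09 to 1.38% in the others) and 2.61% from ribosomal protein genes (3.57 to 4.18% in the others). H2BHi-MMPLo 2 scored −51.2 on the second component (17.2%). The 3 H2BLo-MMPHi libraries lay together at 24.5 to 27.0 on the first component. Settings that ended a call are named below in short: no filter (on low values), CPM from 5 (mean of at least 5), quantile, centring (median) and ratios (median-of-ratios) for scaling, no trend (of variance), weights (of libraries), voom, block (by replicate), robust, groups alone (those compared) and both out (H2BHi-MMPLo 1 and 2).

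**Figure D1:**
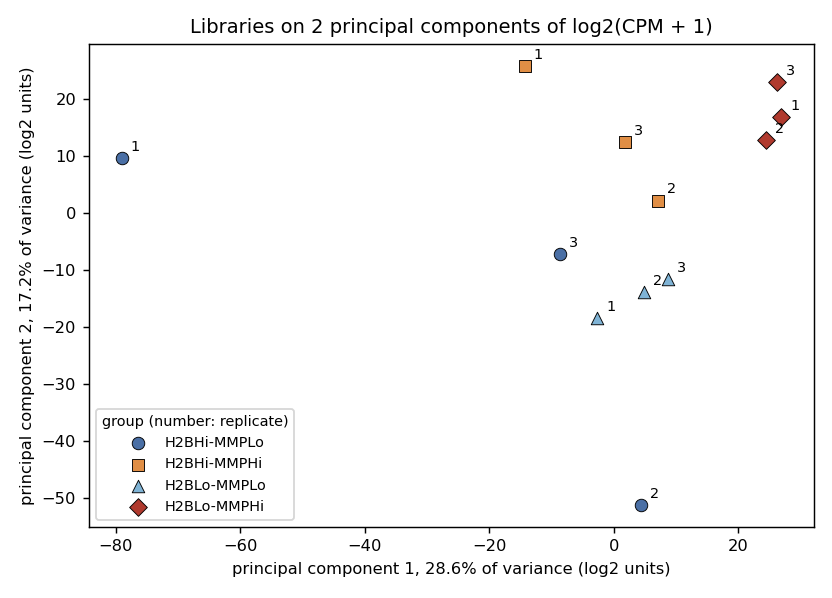
Principal components of log2(CPM + 1) over the 13317 genes tested, with 1 point per library and a colour per group, first component (28.6% of the variance) on the x axis and second (17.2%) on the y axis. H2BHi-MMPLo 1 sits at −79.0 on the first component and the 3 H2BLo-MMPHi libraries at 24.5 to 27.0.

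The first question was how HSCs with high MMP differ from those with low MMP, averaged over both H2B levels. MMPHi cells had more mRNA of genes that carry cells through mitosis. Ccnb1, the cyclin that starts mitosis with Cdk1, rose 2.92-fold (log2 1.54, SE 0.13, adjusted p = 7.95e-05): from 125.8 ± 30.03 to 357.1 ± 48.4 CPM in H2BHi cells and from 167.2 ± 15.9 to 500.7 ± 74.8 in H2BLo cells. Its partner cyclin Ccnb2 rose 2.78-fold (log2 1.47, SE 0.13, adjusted p = 7.95e-05), and Cenpa, the histone variant that marks centromeres, rose 3.92-fold (log2 1.97, SE 0.20, adjusted p = 0.000268). The proliferation marker Mki67 rose 1.64-fold (log2 0.71, SE 0.11, adjusted p = 0.00636), from 156.6 ± 31.1 to 271.8 ± 26.7 CPM in H2BHi cells and from 192.0 ± 21.4 to 295.5 ± 42.6 in H2BLo cells. Cdk6, the kinase that brings cells out of quiescence, rose 1.85-fold (log2 0.89, SE 0.11, adjusted p = 0.00118). Of the 28 G2/M and mitosis genes 24 rose and 0 fell (27 higher when adjusted over the list alone), with a median log2 fold change of 0.80 (adjusted p = 1.08e-47, adjusted p = 0.0502 with an estimated correlation). The G1/S and DNA replication genes had a median of −0.11 and were not called (adjusted p = 0.204). In the mm10 genome Ccnb1 lies on chromosome 13 from 100778739 to 100786486, Ccnb2 on chromosome 9 from 70407689 to 70421554, and Cenpa on chromosome 5 from 30666877 to 30674837. All 5 genes passed without each library in turn, and Mki67 missed the threshold when genes with few reads were kept in the test (adjusted p = 0.0526).

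**Figure D2:**
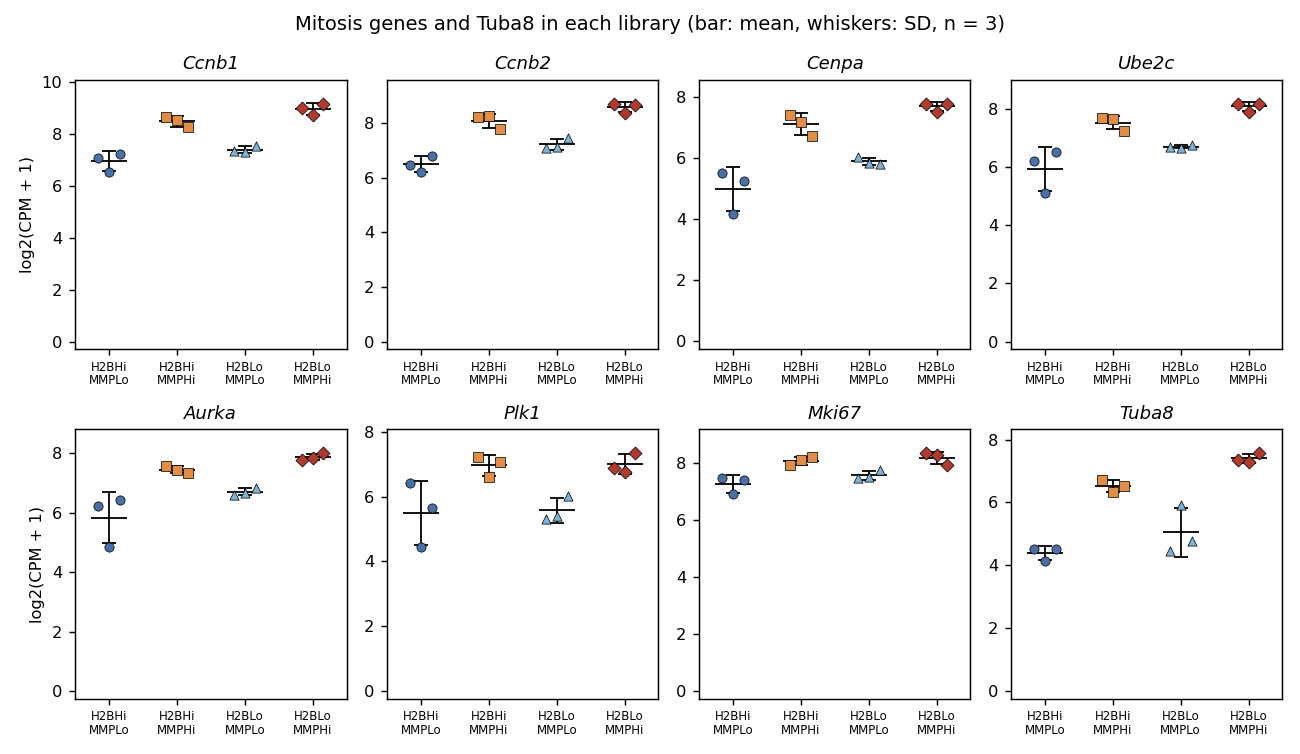
Log2(CPM + 1) of 8 genes in the 4 groups, 1 point per library, bars at the group mean and whiskers of 1 SD (n = 3). Ccnb1, Ccnb2, Cenpa, Ube2c, Aurka, Plk1, Mki67 and Tuba8 each had a higher mean in MMPHi than in MMPLo cells at both H2B levels.

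Procr, which encodes the endothelial protein C receptor, an HSC surface marker, fell 2.53-fold in MMPHi cells (log2 −1.34, SE 0.16, adjusted p = 0.00121): from 132.4 ± 10.5 to 59.8 ± 2.48 CPM in H2BHi cells and from 86.4 ± 12.6 to 30.4 ± 13.3 in H2BLo cells. Ly6a, which encodes Sca-1, fell by 0.70 on the log2 scale (SE 0.10, adjusted p = 0.00362). Hlf, a transcription factor of HSC self-renewal, fell 1.54-fold (log2 −0.62, SE 0.13, adjusted p = 0.0223). Cd48, whose product marks progenitors and is absent from SLAM-sorted HSCs, rose 4.89-fold (log2 2.29, SE 0.34, adjusted p = 0.00374), from 0.309 ± 0.344 to 3.05 ± 2.90 CPM in H2BHi cells and from 0.629 ± 0.620 to 13.2 ± 3.31 in H2BLo cells. Of the 28 HSC identity genes 4 fell and 0 rose (13 lower and 1 higher when adjusted over the list alone; median −0.40, adjusted p = 1.05e-05, adjusted p = 0.130 with an estimated correlation). The 4 were Procr, Ly6a, Hlf and Trim47 (log2 −0.67). Of 8 multipotent progenitor markers Cd48 rose and 0 fell (3 higher and 1 lower when adjusted over the list alone; median 0.25, adjusted p = 0.00703, adjusted p = 0.228 with an estimated correlation). Of 22 CDK inhibitors and quiescence regulators Txnip (log2 −1.0, adjusted p = 0.0106) and Ndn (log2 −0.59, adjusted p = 0.0433) fell (11 lower and 1 higher when adjusted over the list alone; median −0.41, adjusted p = 0.00357, adjusted p = 0.130 with an estimated correlation). Procr lies on chromosome 2 from 155751125 to 155755478, Hlf on chromosome 11 from 90336535 to 90390917 and Cd48 on chromosome 1 from 171681245 to 171705258. The call of Hlf was lost without H2BHi-MMPHi 1 or 3, H2BLo-MMPLo 1 or H2BLo-MMPHi 3 (adjusted p up to 0.0746), that of Trim47 held only without H2BHi-MMPLo 1 or 2 or H2BLo-MMPLo 3 (otherwise up to 0.120) and that of Ndn only without H2BHi-MMPLo 1 or 2 or H2BLo-MMPHi 2 (up to 0.125). With no filter on low values Ly6a, Cd48 and Txnip had adjusted p = 0.0505, 0.0552 and 0.0895, and with voom weights Cd48 had 0.0663. The progenitor median was 0.39 without H2BLo-MMPLo 1. The progenitor call ended among genes with a mean of at least 5 CPM (0.306). Gene calls ended with no filter (Hlf, Trim47, Ndn), quantile (Trim47, Ndn), centring (Hlf, Trim47, Ndn), no trend (Hlf, Trim47, Ndn), block (Ndn), voom (Trim47, Ndn), ratios (Trim47, Ndn) and both out (Hlf, Trim47).

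**Figure D3:**
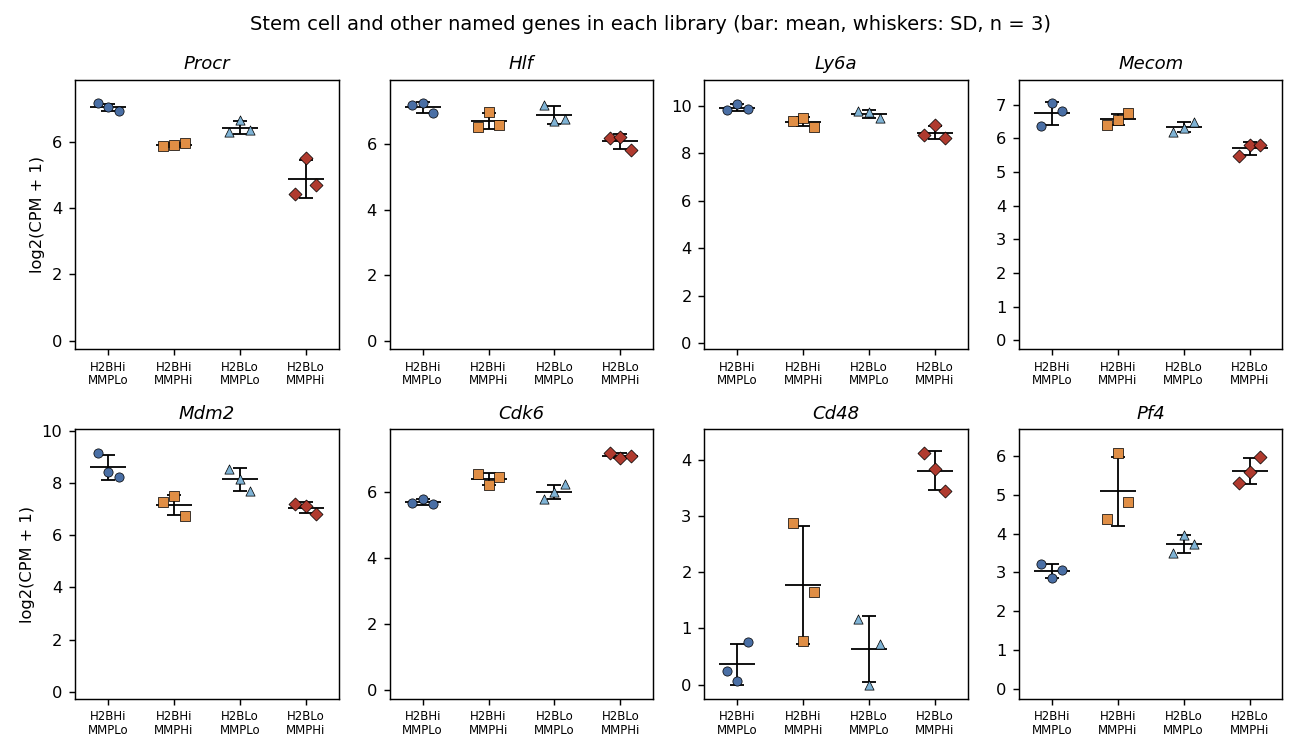
Log2(CPM + 1) of 8 genes in the 4 groups, 1 point per library, bars at the group mean and whiskers of 1 SD (n = 3). Mean Procr, Hlf, Ly6a, Mecom and Mdm2 were lower, and mean Cdk6, Cd48 and Pf4 higher, in MMPHi than in MMPLo cells at both H2B levels; the test of Mecom did not pass (adjusted p = 0.121).

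The remaining fixed markers of HSC state did not pass in the averaged comparison. The CPM of Mecom, an HSC transcription factor, was 108.5 ± 24.4 in H2BHi-MMPLo, 94.3 ± 11.4 in H2BHi-MMPHi, 80.0 ± 8.29 in H2BLo-MMPLo and 51.3 ± 6.47 in H2BLo-MMPHi (log2 −0.41, adjusted p = 0.121). The log2 fold change was −0.35 for Slamf1 (CD150; adjusted p = 0.485), −0.40 for Mllt3 (0.174), −0.48 for Vwf (0.405), 0.61 for Flt3 (0.223) and 0.30 for Cd34 (0.290). It was −1.0 for Cdkn1c, the CDK inhibitor p57 (adjusted p = 0.0651), −0.34 for Ccnd1 (0.164), 0.11 for Myc (0.646), −0.41 for the transferrin receptor Tfrc (0.197), −0.08 for the glucose transporter Slc2a1 (0.916), −0.93 for the lysosome regulator Tfeb (0.151) and 1.11 for Itga2b (0.0530). Mpo, the granule enzyme of myeloid progenitors, was at most 0.193 CPM in every library and was not tested.

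Mdm2, the ubiquitin ligase of p53 and its target, fell 2.39-fold in MMPHi cells (log2 −1.26, SE 0.18, adjusted p = 0.00314), from 399.5 ± 139.7 to 144.9 ± 37.4 CPM in H2BHi cells and from 287.0 ± 82.3 to 131.9 ± 18.1 in H2BLo cells. Gdf15, a stress cytokine, fell 6.15-fold (log2 −2.62, SE 0.48, adjusted p = 0.0115), and the interferon-induced Mx2, a transcribed pseudogene in RefSeq, fell 6.45-fold (log2 −2.69, SE 0.46, adjusted p = 0.00787), with 20.9 ± 25.98 CPM in H2BHi-MMPLo and 5.14 ± 0.881 in H2BLo-MMPLo cells. Ndnf (4.75-fold), the epoxide hydrolase Ephx1 (3.59-fold) and the TAM receptor ligand Gas6 (3.5-fold) fell too. Of 21 p53 target genes 5 fell and 0 rose: Mdm2, Perp (log2 −1.50), Pmaip1 (−2.31), Trp53inp1 (−1.51) and Phlda3 (−1.59), the last named after its value was seen. The p53 list had a median of −0.67 (11 lower when adjusted over the list alone; adjusted p = 1.69e-07, adjusted p = 0.206 with an estimated correlation). Of 17 NF-kB response genes Traf1 (log2 −1.80), Relb (−1.63), Nfkbia (−0.97) and Rel (−0.87) fell (5 lower and 1 higher when adjusted over the list alone; median −0.76, adjusted p = 0.000352, adjusted p = 0.265 with an estimated correlation). Of 23 interferon response genes Gbp2 fell (log2 −0.90, adjusted p = 0.00208; 10 lower and 1 higher when adjusted over the list alone; median −0.40, list adjusted p = 4.14e-06, adjusted p = 0.130 with an estimated correlation); Gbp2 belongs to a family of near-identical genes, so its value is uncertain. None of 14 immediate early genes passed alone over all genes (10 lower when adjusted over the list alone, among them Egr1 at −0.84; median −0.76, adjusted p = 4.14e-06, adjusted p = 0.206 with an estimated correlation). Mdm2 lies on chromosome 10 from 117688875 to 117710758. Without H2BHi-MMPLo 1 the NF-kB median was −0.38. Phlda3 missed the threshold without H2BHi-MMPHi 1 or 3, H2BLo-MMPLo 1 or 2 or H2BLo-MMPHi 3 (adjusted p up to 0.0783). Pmaip1 missed it without H2BLo-MMPLo 1 or H2BLo-MMPHi 1 or 3 (up to 0.0514) and Trp53inp1 without H2BHi-MMPHi 3, H2BLo-MMPLo 1 or 2 or H2BLo-MMPHi 3 (up to 0.0739). The call of Relb was lost without H2BHi-MMPHi 2, H2BLo-MMPLo 1 or 2 or H2BLo-MMPHi 1 or 3 (up to 0.0632) and that of Nfkbia without H2BHi-MMPHi 1 or 3 or H2BLo-MMPHi 1 or 3 (up to 0.0655). Rel passed only without H2BHi-MMPLo 1 or 3 or H2BLo-MMPLo 3 (otherwise up to 0.0955). With no filter on low values Gbp2 passed, while Mdm2, Perp, Traf1, Gas6, Ndnf, Ephx1, Mx2 and Gdf15 had adjusted p = 0.0505, 0.0544, 0.0564, 0.0564, 0.0780, 0.0797, 0.0900 and 0.113. Pmaip1, Trp53inp1, Phlda3, Relb, Nfkbia and Rel missed it too. For single genes the call ended with quantile (Rel), centring (Rel), no trend (Trp53inp1, Phlda3, Nfkbia), voom (Mx2, Phlda3, Relb), ratios (Rel) and both out (Gdf15, Ephx1, Pmaip1, Trp53inp1, Phlda3, Relb, Nfkbia, Rel).

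Some megakaryocyte and erythroid genes were higher in MMPHi cells, and others (Vwf, Tfrc) had lower means at both H2B levels. Pf4, platelet factor 4, rose 3.90-fold (log2 1.96, SE 0.25, adjusted p = 0.00150), from 7.31 ± 1.03 to 37.8 ± 25.1 CPM in H2BHi cells and from 12.4 ± 2.21 to 49.1 ± 11.8 in H2BLo cells. The alpha-tubulin gene Tuba8 rose 4.76-fold (log2 2.25, SE 0.21, adjusted p = 0.000145), the actin-severing protein gene Scin 5.8-fold (log2 2.54, SE 0.42, adjusted p = 0.00711) and the adaptor gene Lat2 3.16-fold (log2 1.66, SE 0.23, adjusted p = 0.00261). Gata1, the erythroid and megakaryocyte transcription factor, rose by 2.10 on the log2 scale (SE 0.37, adjusted p = 0.00880) and reached 4.01 ± 1.13 CPM in H2BHi-MMPHi and 6.23 ± 5.94 in H2BLo-MMPHi cells. Of 14 megakaryocyte and platelet markers Pf4 and F2rl2 rose (6 higher when adjusted over the list alone; median 0.11, adjusted p = 0.00116, adjusted p = 0.206 with an estimated correlation), and of 13 erythroid markers Gata1 and Icam4 rose (3 higher when adjusted over the list alone; median 0.21, adjusted p = 0.00772, adjusted p = 0.206 with an estimated correlation). Of 4 macrophage markers the TAM receptor gene Axl fell (log2 −1.26, adjusted p = 0.00814; list median −0.78, adjusted p = 0.0108, adjusted p = 0.206 with an estimated correlation). Adgre1 and C1qa (at most 0.167 CPM) were not tested, so this list cannot gauge macrophages. Of mast cell and basophil markers Gzmb alone had enough reads and rose (log2 2.04, adjusted p = 0.0367). Pf4 lies on chromosome 5 from 90772435 to 90773383 and Tuba8 on chromosome 6 from 121210734 to 121226098. The erythroid call was lost without H2BHi-MMPLo 1 (adjusted p = 0.0883). The erythroid median was 0.34, 0.04 and 0.11 without H2BHi-MMPHi 1, 2 and 3, 0.08 without H2BLo-MMPLo 1 and 0.12 without H2BLo-MMPHi 2. The megakaryocyte median was 0.28, 0.05 and 0.05 without H2BHi-MMPLo 1, 2 and 3, 0.18 without H2BLo-MMPLo 1, and 0.06 without H2BLo-MMPLo 2 or H2BLo-MMPHi 2. The F2rl2 call was lost without H2BLo-MMPLo 1 or H2BLo-MMPHi 1 or 3 (up to 0.0637) and that of Icam4 without H2BLo-MMPHi 1 (0.0586). Gzmb passed only without H2BHi-MMPLo 1 or H2BLo-MMPHi 2 or 3 (otherwise up to 0.0882). With no filter Axl, Icam4, Scin, Gata1, F2rl2 and Gzmb had adjusted p = 0.0563, 0.0564, 0.0797, 0.0797, 0.0833 and 0.176. With voom Gata1, Scin and Gzmb had 0.0782, 0.0847 and 0.125. No filter (erythroid 0.122, macrophage 0.552), weights (erythroid 0.0548) and both out (erythroid 0.0673, macrophage 0.0673) also ended list calls. Settings that ended gene calls were pseudocount 5 (Gzmb), no trend (Gzmb) and both out (F2rl2, Gzmb, Axl).

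In MMPHi cells the 31 mitochondrial ribosome and protein quality control genes had a median of 0.17 (adjusted p = 5.32e-07, or 0.206 with an estimated correlation). For the 26 MYC and ribosome biogenesis genes it was 0.14 (adjusted p = 0.000131, or 0.130 with an estimated correlation). The 77 cytosolic ribosomal protein genes had a median of 0.10 (adjusted p = 2.44e-08, or 0.483 with an estimated correlation). For the 74 nuclear-encoded respiratory chain genes it was 0.09 (adjusted p = 5.17e-07, or 0.442 with an estimated correlation). In these 4 lists 0 genes passed alone over all genes. For 25 TCA cycle and pyruvate dehydrogenase genes the median was 0.05 and the mean −0.007, so that the median and mean differ in sign (adjusted p = 0.0215, adjusted p = 0.130 with an estimated correlation). Of 32 lysosome genes the cathepsin gene Ctss fell (log2 −1.22, adjusted p = 0.00711; list median −0.18, adjusted p = 0.00116, adjusted p = 0.206 with an estimated correlation). Of 17 HSC ageing genes Cd38 fell (log2 −1.23, adjusted p = 0.0310; 5 lower when adjusted over the list alone; list median −0.35, adjusted p = 0.0150, adjusted p = 0.265 with an estimated correlation). Of 18 STAT5 and cytokine feedback genes 2 fell, neither in every setting (list median −0.28, adjusted p = 0.0445, adjusted p = 0.269 with an estimated correlation). Without H2BHi-MMPLo 1 the calls of ribosomal protein (median 0.005, adjusted p = 0.224), respiratory chain (−0.03, 0.490) and STAT5 genes (−0.17, 0.119) were lost and the mitochondrial ribosome median was 0.09. Without H2BHi-MMPLo 2 the medians were 0.07 for MYC, 0.17 for ribosomal protein and 0.16 for respiratory chain genes (0.14 without H2BHi-MMPLo 3). The TCA median was 0.01 without H2BHi-MMPLo 2, 0.03 without H2BHi-MMPHi 3 and 0.02 without H2BLo-MMPLo 3 or H2BLo-MMPHi 3. The STAT5 call was also lost without H2BHi-MMPHi 2 (0.106), H2BLo-MMPLo 1 (0.0608) or 3 (0.0683) or H2BLo-MMPHi 1 (0.0625) or 2 (0.0599), and the ageing list's without H2BLo-MMPHi 1 (median −0.17, adjusted p = 0.0825; −0.23 without H2BHi-MMPHi 2). Cd38 passed only without H2BHi-MMPLo 1 or 3, H2BHi-MMPHi 3, H2BLo-MMPLo 3 or H2BLo-MMPHi 2 (otherwise up to 0.0821). List calls ended with pseudocount 0.1 (STAT5 0.0617), quantile (TCA 0.323), centring (STAT5 0.0528), no trend (STAT5 0.0802), weights (TCA 0.0548), voom (STAT5 0.0849) and both out (TCA 0.0673, STAT5 0.0817, ageing 0.0817). Other gene calls ended with no filter (Ctss, Cd38), quantile (Cd38), no trend (Cd38) and both out (Cd38).

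Like the G1/S list, the remaining lists were not called in the averaged MMP comparison. The median log2 fold change was 0.15 for 20 ATF4 and amino acid response genes (adjusted p = 0.0506) and −0.30 for 8 dye efflux transporters (0.0963). It was 0.02 for 21 cholesterol synthesis genes (0.0963), 0.06 for 20 ER protein folding genes (0.144) and −0.24 for 5 granulocyte and monocyte markers (0.204). Autophagy and mitophagy genes had a median of −0.14 (adjusted p = 0.204), mitochondrial dynamics and biogenesis genes −0.01 (0.206), glycolysis genes 0.02 (0.309), fatty acid oxidation genes −0.001 (0.407) and hypoxia response genes −0.08 (0.472). The mitochondrial calcium uptake and VDAC genes had a median of −0.25 (0.495), antioxidant genes −0.09 (0.495), stroma and endothelium markers −0.30 (0.720) and mitochondrially encoded genes −0.03 (0.790). The 3 lymphoid markers had a median of −0.20 and a mean of 0.33 (0.720), with Nkg7 passing alone (log2 1.59, adjusted p = 0.00673). Nkg7 missed the threshold with no filter (0.0531).

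Counted over all 13317 genes, 295 passed in the averaged MMP comparison, 121 higher and 174 lower in MMPHi cells, and 19 of 35 lists were called, 9 higher and 10 lower. The balance of directions turned with the scaling: 41.0% of the genes that passed were higher here, against 58.5% with quantile normalization, 67.5% with median centring and 57.1% with median-of-ratios size factors. The median of all genes was −0.06, and centring each library on its median moved it to 0.06, so small list medians are best read relative to that shift. The gene count was 180, 166 and 189 without H2BHi-MMPHi 1, 2 and 3, 477 without H2BHi-MMPLo 1, 134 and 131 without H2BLo-MMPHi 1 and 3, 139 and 166 without H2BLo-MMPLo 1 and 2, and 160 without H2BHi-MMPLo 1 and 2 together; it was 74 with no filter on low values and 745 with library weights. With an estimated correlation 0 of the 35 lists were called (19 with the preset one). Fry, another test in limma, called 17, but 1 for MMP in H2BHi, 7 in H2BLo, 3 for H2B averaged and 0 in the other comparisons.

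Within H2BHi cells the same comparison asks what MMP parts among cells with a high H2B level. Ccnb2 rose 3.01-fold in MMPHi cells (log2 1.59, SE 0.18, adjusted p = 0.00400), from 90.4 ± 19.1 to 273.3 ± 46.3 CPM, and Ccnb1 2.86-fold (log2 1.52, SE 0.18, adjusted p = 0.00400). Tuba8 rose 4.42-fold (log2 2.15, SE 0.29, adjusted p = 0.00999), Cenpa 4.41-fold (log2 2.14, SE 0.28, adjusted p = 0.00999) and Pf4 4.12-fold (adjusted p = 0.0457). The mitotic kinase gene Aurka (adjusted p = 0.0457) and the ubiquitin-conjugating Ube2c (adjusted p = 0.0398) rose 3.07-fold and 3.01-fold. Mdm2 fell 2.71-fold (log2 −1.44, SE 0.26, adjusted p = 0.0457) and the histone gene Hist1h4h 6.23-fold, from 39.5 ± 13.6 to 5.64 ± 3.09 CPM (adjusted p = 0.0477), a value left uncertain by its near-identical gene family. Of the fixed genes Procr had a log2 fold change of −1.13 (adjusted p = 0.0821), Mki67 0.81 (0.0807), Cdk6 0.70 (0.110), Gata1 2.05 (0.175) and Cd48 1.41 (0.379). In all 23 genes passed, 19 higher and 4 lower, and 11.5% of all genes had no overlap between groups where chance gives 10%. The calls of Ccnb1 and Ccnb2 held without each library in turn. Without H2BHi-MMPHi 1 those of Tuba8 (adjusted p = 0.0813) and Cenpa (0.0639) were lost. Aurka and Ube2c passed only without an H2BHi-MMPLo library (otherwise up to 0.192), Pf4 only without H2BHi-MMPLo 1 (up to 0.153). Mdm2 passed only without H2BHi-MMPLo 3 and Hist1h4h only without H2BHi-MMPLo 3 or H2BLo-MMPHi 2 (both up to 0.249). The count was 39 without H2BHi-MMPLo 1 or 3, 9 without H2BHi-MMPLo 2, 2, 6 and 10 without H2BHi-MMPHi 1, 2 and 3, 12, 9 and 7 without H2BLo-MMPLo 1, 2 and 3, and 6, 9 and 6 without H2BLo-MMPHi 1, 2 and 3. It was 3 with no filter on low values, 0 from these 6 libraries alone (23 from all 12; 1169 at an unadjusted p under 0.05; 16 with voom weights), 0 without the variance trend, 56 with library weights and 1 without H2BHi-MMPLo 1 and 2 together. Genes fell short with pseudocount 0.1 (Aurka, Mdm2, Hist1h4h), pseudocount 5 (Pf4, Mdm2, Hist1h4h), weights (Hist1h4h) and voom (Pf4, Mdm2, Hist1h4h). With no filter, no trend or the groups alone none of the genes named here passed, and with both out Cenpa did.

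Among gene lists in H2BHi cells, 9 of 28 G2/M and mitosis genes rose (26 higher when adjusted over the list alone; median 0.87, adjusted p = 4.12e-47, adjusted p = 0.0522 with an estimated correlation). Of 21 p53 target genes Mdm2 fell (9 lower when adjusted over the list alone; median −0.78, adjusted p = 8.69e-10, adjusted p = 0.182 with an estimated correlation). Interferon response genes had a median of −0.50 (Ifit3 −1.34; adjusted p = 3.34e-06, adjusted p = 0.182 with an estimated correlation). For NF-kB response genes it was −1.04 (Relb −2.05, SE 0.47; 4 lower when adjusted over the list alone; adjusted p = 5.21e-06, adjusted p = 0.214 with an estimated correlation). Of megakaryocyte and platelet markers Pf4 rose (median 0.23, adjusted p = 0.000632, adjusted p = 0.182 with an estimated correlation). These 5 calls held without each library in turn, with medians that moved to −0.44 for NF-kB and 0.57 for megakaryocyte genes without H2BHi-MMPLo 1 and to 0.12 for megakaryocyte genes without H2BHi-MMPLo 2. Immediate early genes had a median of −0.65 (Klf6 lower when adjusted over the list alone; adjusted p = 3.00e-05, adjusted p = 0.272 with an estimated correlation). For erythroid markers it was 0.28 (Hba-a1 2.23, uncertain beside its near-identical copy Hba-a2; adjusted p = 0.00312, adjusted p = 0.182 with an estimated correlation). For MYC and ribosome biogenesis genes it was 0.10 (adjusted p = 0.00782, adjusted p = 0.182 with an estimated correlation). HSC identity genes had a median of −0.25 (Procr and Ly6a lower when adjusted over the list alone; adjusted p = 0.0131, adjusted p = 0.296 with an estimated correlation). For CDK inhibitors and quiescence regulators it was −0.40 (Txnip −1.05, Gfi1 −1.91 and Cdkn1a −1.18, with Cdkn2d at 0.56; adjusted p = 0.0131, adjusted p = 0.182 with an estimated correlation). Macrophage markers had a median of −0.77 (Axl −1.0; adjusted p = 0.0316, adjusted p = 0.272 with an estimated correlation). For lysosome genes it was −0.15 (adjusted p = 0.0414, adjusted p = 0.379 with an estimated correlation). Ribosomal protein genes had a median of 0.17 (adjusted p = 2.50e-14, adjusted p = 0.440 with an estimated correlation). For respiratory chain genes it was 0.15 (adjusted p = 9.49e-09, adjusted p = 0.440 with an estimated correlation). For mitochondrial ribosome genes it was 0.21 (adjusted p = 1.00e-07, adjusted p = 0.214 with an estimated correlation). Without H2BHi-MMPLo 1 ribosomal protein genes were at −0.02 (adjusted p = 0.384), respiratory chain genes turned to −0.09 (0.0259) and mitochondrial ribosome genes were at 0.04 (0.0862). Its removal also ended the calls of HSC identity (−0.16, 0.139), immediate early (−0.39, 0.0708), CDK inhibitor (0.0708), erythroid (0.18, 0.151), macrophage (−0.47, 0.222) and lysosome genes (−0.09, 0.120). Without H2BHi-MMPLo 2 the medians were 0.31 for ribosomal protein, 0.29 for respiratory chain and 0.52 for erythroid genes. Without H2BHi-MMPLo 3 they were 0.23 for respiratory chain and 0.16 for MYC genes, without H2BHi-MMPHi 1 0.49 for erythroid genes, and without H2BHi-MMPHi 2 0.16 for MYC and 0.11 for erythroid genes. H2BHi-MMPHi 1 carried the calls of HSC identity (−0.10, 0.102 without it), CDK inhibitor (0.0938) and MYC genes (0.02, 0.159). H2BHi-MMPLo 2 carried those of CDK inhibitor (0.0780), MYC (−0.05, 0.139), lysosome (0.104) and macrophage genes (0.0780; immediate early median −1.05 without it). Erythroid, lysosome and macrophage calls were lost without H2BHi-MMPHi 2 (0.0543, 0.0551, 0.0708), the last 2 without H2BHi-MMPHi 3 (0.180 with a lysosome median of −0.09, 0.0962) and the lysosome call without H2BLo-MMPLo 1 (0.0512). Choices that ended list calls were no filter (erythroid 0.0748, macrophage 0.731, where camera's direction turned to higher at a median of −0.12), quantile (MYC 0.139), centring (lysosome 0.141), no trend (lysosome 0.1003), weights (HSC identity 0.265, CDK inhibitor 0.159, MYC 0.0878, respiratory chain 0.108, lysosome 0.0969, macrophage 0.223), groups alone (lysosome 0.0571), ratios (lysosome 0.110) and both out (HSC identity 0.383, CDK inhibitor 0.464, MYC 0.117, mitochondrial ribosome 0.210, respiratory chain 0.966, median −0.02, lysosome 0.252, erythroid 0.0957, macrophage 0.525).

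Within H2BLo cells the comparison asks what MMP parts among cells with a low H2B level. Cd48 rose 9.0-fold in MMPHi cells (log2 3.17, SE 0.48, adjusted p = 0.0173) and Cdk6 2.12-fold (log2 1.09, SE 0.15, adjusted p = 0.0130), from 63.1 ± 9.59 to 134.3 ± 7.45 CPM. Procr fell 2.93-fold (log2 −1.55, SE 0.23, adjusted p = 0.0173), Ly6a by 0.80 on the log2 scale (SE 0.15, adjusted p = 0.0368) and the cathepsin gene Ctss 3.29-fold (log2 −1.72, SE 0.28, adjusted p = 0.0255). Ccnb1 rose 2.97-fold (log2 1.57, SE 0.18, adjusted p = 0.00426) and Tuba8 5.13-fold (log2 2.36, SE 0.29, adjusted p = 0.00560), from 35.5 ± 21.2 to 168.5 ± 17.4 CPM. Scin rose 9.05-fold (adjusted p = 0.0388), Lat2 3.66-fold (0.0280) and the immune adaptor gene Clnk 3.63-fold (0.0280), from 10.2 ± 4.56 to 38.0 ± 9.10 CPM. Lower genes included the small GTPase gene Rras (log2 −1.55, adjusted p = 0.0173), Plbd1 (−1.92, 0.0173) and the growth factor receptor gene Fgfr1 (−1.46, 0.0369). Among fixed genes that did not pass, Hlf had −0.81 (adjusted p = 0.0800), Mecom −0.63 (0.177), Mki67 0.61 (0.138), Itga2b 1.46 (0.141), Gata1 2.15 (0.107) and Flt3 1.00 (0.274). In all 56 genes passed, 31 higher and 25 lower, and 25.0% of all genes had no overlap between groups where chance gives 10%. Tuba8 (adjusted p = 0.0693) and Ccnb1 (0.0543) missed the threshold only without H2BLo-MMPHi 3. Cd48 (up to 0.130), Procr (up to 0.116), Cdk6 (up to 0.116), Lat2, Clnk, Ctss, Rras, Plbd1 and Ly6a missed it without H2BLo-MMPLo 1 or 2 or H2BLo-MMPHi 1 or 3, and these except Cdk6 and Plbd1 also without H2BLo-MMPLo 3. Ly6a missed it without H2BHi-MMPHi 1 too. Scin passed only without an H2BHi-MMPLo library, H2BHi-MMPHi 1 or H2BLo-MMPLo 3 (otherwise up to 0.223). Fgfr1 passed only without an H2BHi-MMPLo library or H2BHi-MMPHi 1 or 3 (up to 0.211). The count was 3, 34 and 0 without H2BLo-MMPHi 1, 2 and 3, 3, 3 and 8 without H2BLo-MMPLo 1, 2 and 3, 35, 31 and 32 without H2BHi-MMPHi 1, 2 and 3, and 180 and 97 without H2BHi-MMPLo 1 and 2. At the reported setting 1440 genes had an unadjusted p under 0.05. With no filter on low values 2 genes passed, with voom weights 31, with quantile normalization 36, without the variance trend 16, with library weights 587 and from these 6 libraries alone 319. Of these genes, some missed the threshold with pseudocount 0.1 (Cd48, Scin), pseudocount 5 (Fgfr1), quantile (Ctss, Fgfr1), centring (Ly6a), no trend (Procr, Ly6a, Ctss, Scin, Lat2, Clnk, Fgfr1), voom (Cd48, Scin, Fgfr1) and ratios (Ly6a). With no filter none of the genes named here passed.

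Among gene lists in H2BLo cells, 7 of 28 G2/M and mitosis genes rose (26 higher when adjusted over the list alone; median 0.75, adjusted p = 1.50e-38, adjusted p = 0.0954 with an estimated correlation). Of 28 HSC identity genes Procr and Ly6a fell (12 lower and 1 higher when adjusted over the list alone, Tcf15 at −1.83 and Hlf at −0.81 among them; median −0.58, adjusted p = 6.94e-07, adjusted p = 0.134 with an estimated correlation). Cd48 rose among 8 multipotent progenitor markers (Cd52 1.08 and Flt3 1.00, with Lsp1 at −0.52; median 0.29, adjusted p = 0.00137, adjusted p = 0.215 with an estimated correlation), and HSC ageing genes had a median of −0.54 (Clu −0.64 and Clec1a −0.72, lower when adjusted over the list alone; adjusted p = 0.000815, adjusted p = 0.215 with an estimated correlation). P53 target genes had a median of −0.59 (adjusted p = 0.000815, adjusted p = 0.335 with an estimated correlation). Ctss fell among lysosome genes (median −0.22, adjusted p = 0.000837, adjusted p = 0.215 with an estimated correlation) and interferon response genes had a median of −0.37 (adjusted p = 0.000837, adjusted p = 0.215 with an estimated correlation). Immediate early genes had a median of −0.87 (Jund −1.05, Egr1 −1.10; adjusted p = 0.000175, adjusted p = 0.282 with an estimated correlation). For MYC and ribosome biogenesis genes it was 0.18 (adjusted p = 0.000469, adjusted p = 0.134 with an estimated correlation). For mitochondrial ribosome genes it was 0.12 (adjusted p = 0.00129, adjusted p = 0.357 with an estimated correlation). For respiratory chain genes it was 0.05 (adjusted p = 0.00444, adjusted p = 0.637 with an estimated correlation). CDK inhibitors and quiescence regulators had a median of −0.34 (Ndn −0.82; adjusted p = 0.0105, adjusted p = 0.215 with an estimated correlation). For megakaryocyte and platelet markers it was 0.23 (adjusted p = 0.0106, adjusted p = 0.281 with an estimated correlation). For macrophage markers the median was −0.96 (Axl −1.51; adjusted p = 0.0230, adjusted p = 0.281 with an estimated correlation). ATF4 and amino acid response genes had a median of 0.15 (adjusted p = 0.0397, adjusted p = 0.335 with an estimated correlation). For ribosomal protein genes it was 0.02 (adjusted p = 0.0397, adjusted p = 0.766 with an estimated correlation). Calls lost without 1 library were those of ribosomal protein genes (H2BLo-MMPLo 2, adjusted p = 0.132, or 3, 0.0975; H2BLo-MMPHi 1, 0.0976, or 2, 0.195) and ATF4 genes (H2BLo-MMPLo 1, 0.0571, or 3, 0.0949; H2BLo-MMPHi 3, 0.123). Further losses were those of macrophage markers (H2BLo-MMPLo 1, 0.108, or 2, 0.0547), megakaryocyte markers (H2BLo-MMPHi 2, 0.106) and CDK inhibitors (H2BLo-MMPHi 3, 0.0538). The progenitor median was 0.59 without H2BLo-MMPLo 1, 0.15 without H2BLo-MMPLo 3 and 0.17 without H2BLo-MMPHi 1. That of p53 targets was −0.37 without H2BLo-MMPLo 1, of ageing genes −0.33 without H2BLo-MMPHi 1, and of respiratory chain and megakaryocyte genes 0.01 and 0.12 without H2BLo-MMPLo 2. The megakaryocyte median was also 0.12 and that of ATF4 genes 0.22 without H2BLo-MMPHi 2. The ribosomal protein median was 0.05 without H2BLo-MMPLo 1, 0.06 without H2BLo-MMPHi 3 and 0.01 without H2BLo-MMPLo 2 or H2BLo-MMPHi 2. Of the list calls, some ended with no filter (ribosomal protein 0.0649, macrophage 0.111), CPM from 5 (progenitor 0.162, ribosomal protein 0.0599, megakaryocyte 0.162), quantile (ribosomal protein 0.431, median −0.02, mitochondrial ribosome 0.0609, respiratory chain 0.615, ATF4 0.0930), no trend (ribosomal protein 0.0514, ATF4 0.0514), groups alone (macrophage 0.0595) and voom (ribosomal protein 0.0592, macrophage 0.0620).

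**Figure D4:**
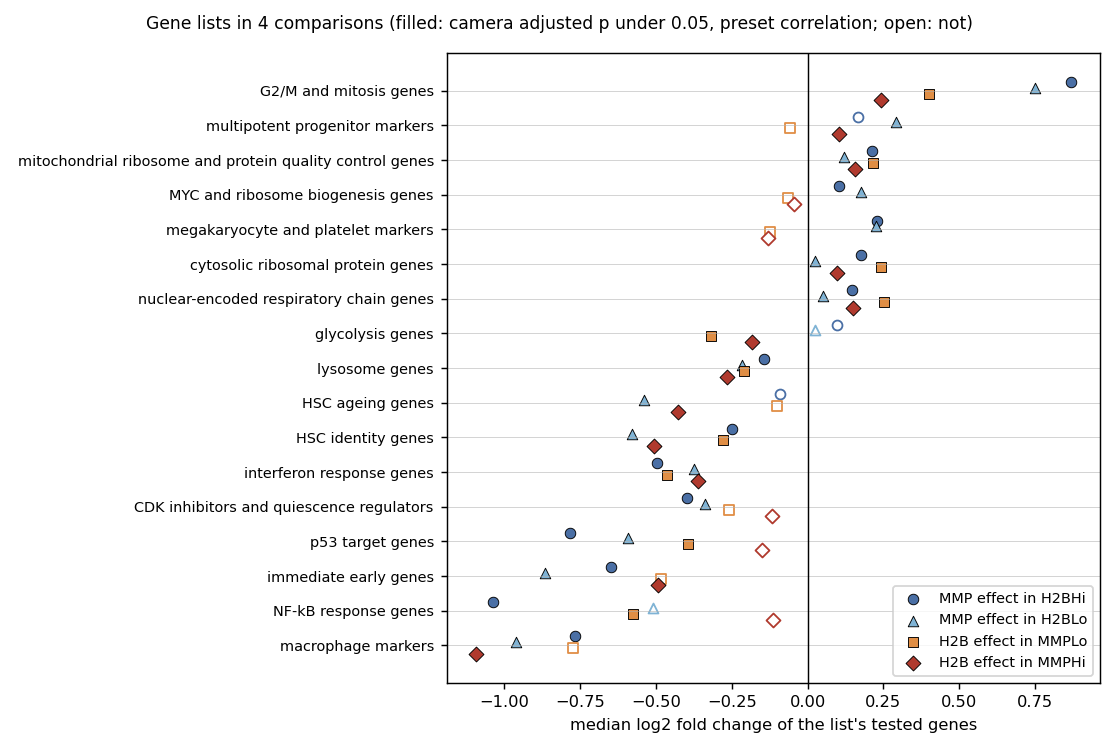
Median log2 fold change of the genes in each of 17 lists (y axis) in the 4 comparisons within a level of MMP or H2B, with filled points where camera's adjusted p was under 0.05. G2/M and mitosis genes had the highest medians for MMP, 0.87 in H2BHi and 0.75 in H2BLo cells, and ribosomal protein genes in H2BLo cells turned from 0.02 to −0.02 under quantile normalization.

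The MMP fold changes at the 2 H2B levels share no library, but the variance behind the calls is pooled over all 12, so a gene of low variance passes more easily at both levels. Of 19 genes higher in MMPHi cells in H2BHi and 31 in H2BLo cells, 15 were shared, and the number to expect under this shared variance was not worked out. They were Ccnb1, Ccnb2, Cdkn3, Cenpa, Cenpe, Hmmr, Kpna2, Nuf2, Pf4, Prc1, Pttg1, Slc22a3, Tpx2, Tuba8 and Ube2c. Of 4 and 25 lower genes 1 was shared: the growth factor gene Igf1, named after its values were seen, which fell by 2.26 on the log2 scale in H2BHi cells (adjusted p = 0.0457) and by 2.08 in H2BLo cells (adjusted p = 0.0452). Igf1 passed in H2BHi cells only without H2BHi-MMPHi 3 (otherwise up to 0.213) and in H2BLo cells only without H2BHi-MMPLo 1 or 2 or H2BHi-MMPHi 1 or 3 (up to 0.239). Igf1 missed the threshold in H2BHi cells with pseudocount 0.1, no filter, quantile, no trend, groups alone, voom and both out. In H2BLo cells it did so with pseudocount 0.1, no filter, quantile, centring, no trend and voom. The 15 shared higher genes became 24 and 9 without H2BHi-MMPLo 1 and 2, 2, 4 and 6 without H2BHi-MMPHi 1, 2 and 3, 2, 2 and 3 without H2BLo-MMPLo 1, 2 and 3, and 2, 6 and 0 without H2BLo-MMPHi 1, 2 and 3. Across the 13317 genes, which are not independent replicates, the log2 fold changes at both levels had a Pearson r of 0.438, and 66.7% had the same sign.

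The second question was how HSCs with a low H2B level differ from those with a high one. The list calls given for it rest on camera's preset correlation, and 0 were made with an estimated one. In MMPLo cells the CPM of Cenpe, a kinesin of the centromere, was 51.9 ± 11.2 in H2BHi and 92.9 ± 19.96 in H2BLo cells (log2 0.83, SE 0.19, adjusted p = 0.478), and that of the interferon-induced GTPase gene Iigp1 was 124.6 ± 11.9 and 69.6 ± 12.03 (log2 −0.84, SE 0.16, adjusted p = 0.478). G2/M and mitosis genes had a median of 0.40 in this comparison (10 higher when adjusted over the list alone, among them Ccnb2 at 0.73; adjusted p = 1.51e-11, adjusted p = 0.625 with an estimated correlation). Ribosomal protein genes had a median of 0.24, all 77 above 0 (Rps8 0.37; adjusted p = 2.10e-21, adjusted p = 0.630 with an estimated correlation). For interferon response genes it was −0.46 (Stat1 −0.56, Irf7 −1.56; adjusted p = 1.92e-05, adjusted p = 0.625 with an estimated correlation). Respiratory chain genes had a median of 0.25 (Cox5a 0.47; adjusted p = 3.68e-14, adjusted p = 0.630 with an estimated correlation). For mitochondrial ribosome genes it was 0.22 (adjusted p = 1.30e-06, adjusted p = 0.625 with an estimated correlation). For mitochondrially encoded genes it was 0.14 (adjusted p = 0.0150, adjusted p = 0.640 with an estimated correlation). HSC identity genes had a median of −0.28 (adjusted p = 0.0216, adjusted p = 0.630 with an estimated correlation). For lysosome genes it was −0.21 (adjusted p = 0.0175, adjusted p = 0.630 with an estimated correlation). For glycolysis genes it was −0.32 (Pfkm −0.97; adjusted p = 0.0201, adjusted p = 0.640 with an estimated correlation). The p53 target genes had a median of −0.39 (adjusted p = 0.0150, adjusted p = 0.640 with an estimated correlation). For NF-kB response genes it was −0.58 (adjusted p = 0.0194, adjusted p = 0.640 with an estimated correlation). With limma 0 genes passed (1250 at an unadjusted p under 0.05; 0 with voom weights; 5 with no filter on low values). The naming rule, which asks for a mean of at least 5 CPM, added Sgol1 (log2 0.84), Dtnbp1 (0.73), Eps8l2 (−2.00) and Igf2bp2 (−1.81). The G2/M, ribosomal protein and interferon calls held without each library, with ribosomal protein medians of 0.04 and 0.38 without H2BHi-MMPLo 1 and 2. Without H2BHi-MMPLo 2 the medians were 0.22 for G2/M, 0.42 for respiratory chain, 0.29 for mitochondrially encoded and −0.53 for glycolysis genes. Removing H2BHi-MMPLo 1 left 4 of the 11 list calls and gave 0.02 for respiratory chain (adjusted p = 0.344), 0.06 for mitochondrial ribosome (0.0712), −0.07 for mitochondrially encoded (0.344) and −0.02 for glycolysis genes (0.852), and adjusted p = 0.0939 for HSC identity and 0.776 for p53 and NF-kB genes (medians −0.15 and −0.27). The p53 median was −0.64 without H2BLo-MMPLo 1. Further losses followed the removal of H2BHi-MMPLo 2 (HSC identity 0.0780, lysosome 0.113), H2BHi-MMPLo 3 (glycolysis 0.0848), H2BLo-MMPLo 2 (p53 0.0571, NF-kB 0.0850) and H2BLo-MMPLo 3, which ended 5 of the 11 calls (HSC identity 0.153, lysosome 0.227, p53 0.227, NF-kB 0.234, glycolysis 0.111, with medians of −0.11 for lysosome, −0.16 for p53 and −0.27 for NF-kB genes). Lists fell short with quantile (mitochondrially encoded 0.0642), centring (lysosome 0.0682), weights (HSC identity 0.281, mitochondrial ribosome 0.0573, mitochondrially encoded 0.471, lysosome 0.0776, p53 0.477, NF-kB 0.477) and both out (HSC identity 0.520, mitochondrial ribosome 0.453, mitochondrially encoded 0.405, lysosome 0.241, p53 0.939, NF-kB 0.930).

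H2BLo and H2BHi cells were also compared among MMPHi cells. Mecom was 94.3 ± 11.4 CPM in H2BHi and 51.3 ± 6.47 in H2BLo cells (log2 −0.87, SE 0.18, adjusted p = 0.477), and Procr had a log2 fold change of −1.03 (adjusted p = 0.480). The chaperone gene Clu was 391.2 ± 35.4 and 226.4 ± 57.6 CPM (log2 −0.81, SE 0.16, adjusted p = 0.477) and Cdk6 82.9 ± 9.81 and 134.3 ± 7.45 (log2 0.69, SE 0.15, adjusted p = 0.477). HSC identity genes had a median of −0.51, 26 of 28 below 0 (9 lower when adjusted over the list alone, among them Mecom, Procr, Hlf at −0.62 and Slamf1 at −1.10; adjusted p = 8.46e-10, adjusted p = 0.153 with an estimated correlation). HSC ageing genes had a median of −0.43 (Clu, Clec1a, Slamf1 and Selp lower when adjusted over the list alone; adjusted p = 7.21e-06, adjusted p = 0.201 with an estimated correlation). For lysosome genes it was −0.27 (Ctss −1.16, Lamp2 −0.36; adjusted p = 2.58e-06, adjusted p = 0.201 with an estimated correlation). G2/M and mitosis genes had a median of 0.24 (27 of 28 above 0, 0 when adjusted over the list alone; adjusted p = 4.08e-11, adjusted p = 0.362 with an estimated correlation). For interferon response genes it was −0.36 (Gbp2 −0.58; adjusted p = 7.52e-05, adjusted p = 0.265 with an estimated correlation). Respiratory chain genes had a median of 0.15 (adjusted p = 8.46e-10, or 0.549 with an estimated correlation). For ribosomal protein genes it was 0.10 (adjusted p = 1.19e-07, or 0.668 with an estimated correlation). For mitochondrial ribosome genes it was 0.16 (adjusted p = 0.000153, or 0.492 with an estimated correlation). Glycolysis genes had a median of −0.18 (adjusted p = 0.0127, or 0.560 with an estimated correlation). For macrophage markers it was −1.09 (adjusted p = 0.0127, or 0.394 with an estimated correlation). For immediate early genes it was −0.49 (adjusted p = 0.0261, or 0.577 with an estimated correlation). For multipotent progenitor markers it was 0.10 (Cd48 2.03; adjusted p = 0.0276, adjusted p = 0.492 with an estimated correlation). With limma 0 genes passed (725 at an unadjusted p under 0.05; 0 with voom weights; 39 with library weights). The smallest adjusted p, 0.0711, was that of Plac8 (log2 2.06), named after its values were seen. With a mean of at least 5 CPM the naming rule added Hmgb3 (log2 0.43), Clnk (1.20), Maged2 (−0.92), Ndn (−0.97) and Axl (−1.48). Calls lost without 1 library were those of glycolysis genes (H2BHi-MMPHi 1, median −0.11, adjusted p = 0.275), macrophage markers (H2BHi-MMPHi 1, 0.0531), immediate early genes (H2BHi-MMPHi 2, 0.150, or 3, 0.0541; H2BLo-MMPHi 1, 0.162) and progenitor markers (H2BHi-MMPLo 1, 0.0711; H2BHi-MMPHi 2, 0.0897, or 3, 0.264; H2BLo-MMPHi 1, 0.229). The progenitor median turned to −0.02 without H2BHi-MMPHi 3 and −0.03 without H2BLo-MMPHi 1, and was 0.28, 0.22 and 0.32 without H2BHi-MMPHi 1, H2BLo-MMPHi 2 and H2BLo-MMPHi 3. Without H2BHi-MMPHi 1 the medians were 0.05 for ribosomal protein, 0.09 for mitochondrial ribosome and respiratory chain and −0.20 for interferon genes. Without H2BLo-MMPHi 2 the ageing median was −0.73. Among MMPHi cells list calls ended with pseudocount 0.1 (progenitor 0.133), pseudocount 5 (immediate early 0.0523), no filter (immediate early 0.0963, macrophage 0.0963), CPM from 5 (progenitor 0.766, median −0.002), quantile (ribosomal protein 0.0656), centring (glycolysis 0.0880), no trend (glycolysis 0.0508), groups alone (progenitor 0.103, macrophage 0.0712), voom (progenitor 0.0529, immediate early 0.0746) and both out (progenitor 0.0873).

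Averaged over MMP, the H2B comparison gave 12 called lists, 5 higher and 7 lower in H2BLo cells. G2/M and mitosis genes had a median of 0.31 (15 higher when adjusted over the list alone; Ccnb2 0.61, SE 0.13, gene adjusted p = 0.149; list adjusted p = 6.66e-15, adjusted p = 0.276 with an estimated correlation). HSC identity genes had a median of −0.40 (13 lower when adjusted over the list alone; adjusted p = 1.85e-06, adjusted p = 0.255 with an estimated correlation). For interferon response genes it was −0.37 (8 lower when adjusted over the list alone; adjusted p = 1.55e-06, adjusted p = 0.255 with an estimated correlation). For lysosome genes it was −0.25 (adjusted p = 2.91e-05, or 0.255 with an estimated correlation). Ribosomal protein genes had a median of 0.17 (adjusted p = 2.08e-19, or 0.575 with an estimated correlation). For respiratory chain genes it was 0.21 (adjusted p = 2.44e-16, or 0.455 with an estimated correlation). For mitochondrial ribosome genes it was 0.16 (adjusted p = 2.56e-07, or 0.347 with an estimated correlation). Glycolysis genes had a median of −0.33 (adjusted p = 0.00348, or 0.588 with an estimated correlation). For HSC ageing genes it was −0.32 (5 lower when adjusted over the list alone; adjusted p = 0.00348, adjusted p = 0.347 with an estimated correlation). For macrophage markers it was −0.94 (adjusted p = 0.0192, adjusted p = 0.347 with an estimated correlation). Immediate early genes had a median of −0.43 (adjusted p = 0.0198, adjusted p = 0.588 with an estimated correlation). For mitochondrially encoded genes it was 0.09 (adjusted p = 0.0460, adjusted p = 0.588 with an estimated correlation). With limma 0 genes passed (1863 at an unadjusted p under 0.05; 0 with voom weights; 158 with library weights). The naming rule gave Iigp1 (log2 −0.69, SE 0.11), Tinagl1 (−1.13), Axl (−1.23) and Ahnak2 (−1.59), each with adjusted p = 0.120, and Cenpe (0.65), Cdk6 (0.50) and Sgol1 (0.60), between 0.149 and 0.165. Without H2BHi-MMPLo 1, 3 genes passed, the mitochondrially encoded (adjusted p = 0.727) and immediate early calls (−0.11, 0.279; −0.67 without H2BHi-MMPLo 2) were lost, and the medians were 0.07 for ribosomal protein, 0.09 for respiratory chain and mitochondrial ribosome and −0.14 for glycolysis genes. There was 1 gene that passed without H2BHi-MMPHi 3 or H2BLo-MMPHi 2. The immediate early call was also lost without H2BHi-MMPHi 2 (0.0572) or H2BLo-MMPHi 1 (0.0527) and the macrophage call without H2BHi-MMPLo 2 (0.0651) or H2BLo-MMPLo 3 (0.0508). The mitochondrially encoded call, whose median was −0.02 without H2BHi-MMPLo 1, held only without H2BHi-MMPLo 2 (median 0.17) or 3, H2BHi-MMPHi 2 or H2BLo-MMPHi 3. Settings costing list calls were no filter (immediate early 0.174, mitochondrially encoded 0.0697, macrophage 0.558), CPM from 5 (mitochondrially encoded 0.0580), quantile (mitochondrially encoded 0.424), no trend (mitochondrially encoded 0.0945), weights (mitochondrially encoded 0.347, macrophage 0.0709) and both out (immediate early 0.106, mitochondrially encoded 0.191, ageing 0.0535, macrophage 0.143).

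The interaction asks whether the MMP difference itself differs between H2B levels. HSC identity genes had a median interaction of −0.25 on the log2 scale, a lower value of MMPHi against MMPLo in H2BLo than in H2BHi cells (Tcf15 −1.55, Hoxb5 −1.25, Mecom −0.45; adjusted p = 0.0133, adjusted p = 0.846 with an estimated correlation). HSC ageing genes had a median of −0.33 (Clu −0.55, Selp −1.07; adjusted p = 0.0133, adjusted p = 0.846 with an estimated correlation). For ribosomal protein genes it was −0.15, all 77 below 0 (adjusted p = 5.28e-06, adjusted p = 0.846 with an estimated correlation). G2/M and mitosis genes had a median of −0.07 and were not called (adjusted p = 0.401), and Cd48 had 1.76 (SE 0.68, adjusted p = 0.999). With limma 0 genes passed (299 at an unadjusted p under 0.05; 0 with voom weights; 2 with no filter on low values; 1 without the variance trend). The smallest adjusted p was 0.999, that also of Zfp455 (log2 2.55), Lat (0.78), Pdxp (−1.88) and Galnt11 (−1.61), from the naming rule. Ribosomal protein genes turned to 0.05 without H2BHi-MMPLo 1 (adjusted p = 0.00311) and to −0.28 without H2BHi-MMPLo 2. The HSC identity call was lost without H2BHi-MMPLo 3 (0.0926), H2BHi-MMPHi 3 (0.131), H2BLo-MMPLo 2 (0.0795) or H2BLo-MMPHi 1 (0.199), and the ageing call without H2BHi-MMPLo 3 (0.0676), H2BHi-MMPHi 3 (0.131) or H2BLo-MMPHi 1 (0.253, median −0.21; −0.54 without H2BHi-MMPLo 1). A list call ended with weights (ribosomal protein 0.534) and both out (ribosomal protein 0.860, direction turned).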

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

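The splits, the removals of 1 library, the scalings other than median-of-ratios size factors and the estimated correlation were planned as runs. The tests built from them for each pattern below, and the tests on marker genes, were chosen after the result was seen. The 3 interaction results below were picked out because the MMP difference itself differed between H2B levels by the preset-correlation test. The median log2 interaction was −0.146 for cytosolic ribosomal protein genes, −0.251 for HSC identity genes and −0.330 for HSC ageing genes (adjusted p = 5.28e-06, 0.0133 and 0.0133; adjusted p = 0.846 with an estimated correlation for each). Chance is not excluded for them. Splits of the 12 libraries cannot decide, as regrouping can carry group differences into the interaction. Of 100, 98 gave as many lists or more (real 3, highest other 17). The ribosomal protein value was 0.05 without H2BHi-MMPLo 1 (adjusted p = 0.00311), the identity call was lost without H2BHi-MMPLo 3, H2BHi-MMPHi 3, H2BLo-MMPLo 2 or H2BLo-MMPHi 1 (0.0926, 0.131, 0.0795 and 0.199), and the ageing call without H2BHi-MMPLo 3, H2BHi-MMPHi 3 or H2BLo-MMPHi 1 (0.0676, 0.131 and 0.253).

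The first pattern is the higher level of G2/M and mitosis genes in MMPHi cells at both H2B levels. The deviating library H2BHi-MMPLo 1 does not account for it, since the median in H2BHi cells was 0.990 without that library, and neither does scaling, since the smallest median over 4 scalings and both comparisons was 0.740. Granulocyte and monocyte progenitors, which the LSK gate would remove, are argued against by Mpo, Elane and Ctsg: together they gained at most 0.0802 CPM (−0.00329 in H2BLo cells), while Mki67 gained 115.2 and 103.5 CPM. Cells primed for megakaryocyte or erythroid fate and CD48-positive progenitors stay open as sources. The megakaryocyte median was 0.115 for MMP averaged, with members either side of 0. Erythroid and progenitor markers were not weighed. A biological difference between HSCs of high and low MMP after culture is a hypothesis beside these.

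The second pattern is the lower level of HSC identity genes with more Cd48 mRNA in MMPHi cells. In H2BHi cells the list call may rest on single libraries: it was lost without H2BHi-MMPLo 1 (adjusted p = 0.139, median −0.164) and also without H2BHi-MMPHi 1 (0.102, median −0.0981). In H2BLo cells no removal of 1 library brought the median closer to 0 than −0.504. CD48-positive multipotent progenitors stay open as a candidate source: the median of 8 progenitor markers was 0.252, with Cd48 higher and Lsp1 lower in MMPHi cells (mean 265.8 to 188.8 CPM in H2BHi and 216.5 to 148.1 in H2BLo cells). The SLAM sort would remove CD48-positive cells, but RNA was taken after culture, and Mpo, which the granulocyte list also holds, stayed at or below 0.193 CPM in every library. A change of HSCs themselves and such cells cannot be told apart here, because RNA was pooled over cells.

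The third pattern is the higher level of ribosomal protein and respiratory chain genes in MMPHi or H2BLo cells. For MMP in H2BHi cells, the library H2BHi-MMPLo 1 is a candidate cause: without it the ribosomal protein median was −0.0234 and the respiratory chain median −0.0911. For H2B in MMPHi cells, which leaves that group out of the contrast, the smaller of both lists' medians stayed at 0.0532 or above without any 1 library, against 1 library as the whole cause there. Why H2BHi-MMPLo 1 differs was not tested.

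In the averaged MMP comparison 1 of 100 splits, the real one, gave 295 genes (highest other 4) and 19 lists (highest other 16). This argues against chance for these totals only. Chance cannot be excluded for the lists of the averaged H2B comparison (12, as large in 6 of 100, highest other 14). Every split reaches a real count of 0, so the splits decide nothing for genes in the averaged H2B comparison (0, 100 of 100, highest other 2) and the interaction (0, 100 of 100, highest other 0), nor for H2B genes within an MMP level. The 10 splits of 6 libraries are too few for a share under 0.05. There MMP gave 23 genes and 15 lists in H2BHi cells (highest other 0 and 11; as large in 1 of 10 for each) and 56 genes and 16 lists in H2BLo cells (0 and 11; 1 of 10 for each). H2B gave 0 genes and 11 lists in MMPLo cells (0 and 11; as large in 10 and 3 of 10), and 0 genes and 12 lists in MMPHi cells (0 and 11; as large in 10 and 1 of 10).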

How the results depend on the processing

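The alternatives were planned, apart from those said to be added after the data were seen. Of 1110 results for named genes, leaving out the filter on low values ended the most calls (71). Of those that passed, 0 reversed direction under the alternatives run. This says little, since the 23 and 56 genes called for MMP within a level had no overlap. The larger shifts of the counts were as follows, with genes called in the order MMP in H2BHi, MMP in H2BLo, H2B in MMPLo, H2B in MMPHi, interaction, MMP averaged and H2B averaged (23, 56, 0, 0, 0, 295 and 0 as reported with limma; 1169, 1440, 1250, 725, 299, 2186 and 1863 at an unadjusted p under 0.05).

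With no filter on low values the gene counts were 3, 2, 5, 1, 2, 74 and 2 (66 of the 74 shared with the 295); 29174 genes with a read could then be tested. Without the variance trend they were 0 and 16 for MMP in H2BHi and H2BLo, and 1 each for H2B in MMPHi, the interaction and H2B averaged. Library weights gave 56 and 587 for MMP in H2BHi and H2BLo, 39 for H2B in MMPHi, 745 for MMP averaged and 158 for H2B averaged, and 5 lists for H2B in MMPLo (11 as reported). From the compared groups alone MMP gave 0 genes in H2BHi and 319 in H2BLo. A pseudocount of 5 gave 1 gene for H2B in MMPHi and 7 lists for the interaction (3 as reported). Quantile normalization gave 36 genes for MMP in H2BLo, 1 for H2B in MMPHi and 8 lists for the interaction; median centring and median-of-ratios size factors each gave 6 lists there. Voom weights gave 31 genes for MMP in H2BLo. Without H2BHi-MMPLo 1 and 2 together, MMP gave 1 gene and 8 lists in H2BHi, 237 genes in H2BLo and 160 averaged, and H2B in MMPLo gave 5 lists; H2BHi-MMPLo 3 was then alone in its group and assumed to vary like the other groups. With an estimated correlation 0 lists were called in each of the 7 comparisons, against 15, 16, 11, 12, 3, 19 and 12 with the preset one. The share of calls that were higher is given above for MMP averaged. For MMP in H2BLo it moved from 55.4% to 77.8% under quantile normalization and 72.4% under median centring. Median centring moved the median of all genes from −0.04 to 0.08 for MMP in H2BHi, −0.06 to 0.07 in H2BLo, −0.06 to 0.08 for H2B in MMPLo and −0.07 to 0.07 in MMPHi. Apart from the removed libraries and the number of genes tested, the cause of these shifts was not tested.

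Leaving out 1 library gave 2 to 39 genes for MMP in H2BHi, 0 to 180 in H2BLo, 131 to 477 averaged, 0 to 3 for H2B averaged, and 0 to 0 for H2B in MMPLo, H2B in MMPHi and the interaction. Lists ranged from 11 to 17, 14 to 20, 4 to 13, 10 to 13, 1 to 9, 18 to 21 and 10 to 14 in the same order of comparisons. The replicate numbers share no stated source, and 4 of 18 correlations between same-numbered libraries' deviations exceeded 0.1 (−0.031 to 0.286); 1 of 12 libraries correlated best with its own number in all 3 other groups. With the replicate block 7 lists were called for the interaction, and 29, 64 and 372 genes for MMP in H2BHi, in H2BLo and averaged. Genes under a mean of 1 CPM, such as Mpo, were not tested. For MMP averaged 38% of simulated 1.5-fold changes were recovered.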

Other observations

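The genes and values in this part were chosen after the data were seen, apart from the marker lists, which were fixed earlier; no explanation was tested. Plac8, a gene of myeloid and lymphoid progenitors, was near absence in 3 groups: 0.0990 ± 0.0437 CPM (SD, n = 3) in H2BHi-MMPLo, 0.481 ± 0.10 in H2BHi-MMPHi and 0.109 ± 0.0357 in H2BLo-MMPLo cells, against 5.19 ± 0.781 in H2BLo-MMPHi cells. It rose in MMPHi cells within H2BLo (limma log2 2.48, adjusted p = 0.00426; 0.0543 without H2BLo-MMPHi 3 and 0.0591 with voom weights), and H2BLo against H2BHi in MMPHi cells it had 2.06 (adjusted p = 0.0711). Igf1, a growth factor gene, had 6.79 ± 1.75 CPM in H2BHi-MMPLo and 6.51 ± 1.59 in H2BLo-MMPLo cells, against 0.779 ± 1.01 and 0.80 ± 0.524 in the MMPHi groups, and fell by 2.17 on the log2 scale in the averaged MMP comparison (SE 0.29, adjusted p = 0.00171).

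Markers of other blood cells differed in abundance. The granule genes Elane and Ctsg were at most 0.605 and 0.482 CPM in any library, and the erythroid genes Car1 and Klf1 at most 0.108 and 5.53. Other genes of the same lists were abundant: group means were 16.3 to 21.8 CPM for the granule gene Prtn3, 277.5 to 310.2 for Lyz2, 125.8 to 158.0 for Hbb-bt and 64.6 to 87.2 for Hbb-bs, the globin genes being near-identical. Hba-a1, which cannot be parted from its near-identical copy, averaged 2.95 CPM in H2BHi-MMPLo, 32.0 in H2BHi-MMPHi, 10.7 in H2BLo-MMPLo and 15.8 in H2BLo-MMPHi cells. The H2BHi-MMPHi mean leaned on 1 library at 75.2 CPM, the highest of all libraries. Gzmb, a cytotoxic granule gene that mast cells and basophils also express, was 0 in all H2BHi-MMPLo and H2BLo-MMPLo libraries, 1.12 ± 0.651 CPM in H2BHi-MMPHi and 12.8 ± 15.3 in H2BLo-MMPHi cells.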
